A study of Homo sapiens with 525 samples.

How the data were processed

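Gene expression was measured in the 60 cell lines of the NCI-60 panel after 2, 6 or 24 h with topotecan at 0, 10 or 1000 nM. Per the labels, the series belongs to a set that follows responses to 15 anticancer agents over time, cells were plated 1 day before the drug, and DMSO was the solvent. Total RNA was labelled with biotin in a 1-cycle Affymetrix kit and hybridised to arrays, also per the labels. The sample labels gave the line, tissue, dose and time of all 525 arrays, and every data column was matched to 1 label. No batch, plate or hybridisation date was given, so no batch could be set beside a comparison other than the tissue.

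The deposited values are log2 expression levels by the authors, and the log base was read from the values, which ran from 2.66 to 14.01. The authors' background correction, normalization and summarization are not given in the sources used here. Array medians lay between 5.06 and 5.47, and the lower and upper quartiles between 3.81 and 4.12 and between 7.52 and 7.96. No step was applied to the deposited values before the main tests. Of 22277 probe sets, 62 were array controls, 19064 had 1 gene in the annotation table supplied with the series, 1043 had several and 2108 had none. Probe sets with several genes or none were left out of the gene tests and counted apart. Each gene was represented by its probe set with the highest mean over all arrays, which gave 11963 genes, of which 4310 had several probe sets. Gene names and lengths came from a RefSeq table of the assembly GRCh38.p14, which gave a length for 11954 genes and was used for nothing else.

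Each comparison was made within lines, as the difference between 2 arrays of the same line, or between 2 such differences for the change between times. Lines without both arrays were left out of that comparison, and 49 lines had all 9 arrays. The pairing was checked with the deviations of each array from its group mean. Arrays of the same line correlated at a median of 0.922 (lowest 0.646, 2045 pairs), and arrays of different lines at -0.0446 (135505 pairs). Differences were tested against 0 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the 11963 genes. The threshold was an adjusted p of 0.05, and called genes also had a mean change of at least 1.5-fold. The dependence on tissue was tested with the moderated F statistic over the 9 tissues on the same differences, and each tissue was then set against all other lines.

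The 19 gene lists were p53 targets, immediate early and AP-1 genes, NF-kB targets, interferon response genes, histone genes, G1/S and DNA replication genes, G2/M and mitosis genes, topoisomerases and drug handling genes, DNA repair and checkpoint genes, genes over 200 kb long, apoptosis regulators, integrated stress and unfolded protein response genes, heat shock genes, cholesterol synthesis genes, nucleolar and ribosome biogenesis genes, ribosomal protein genes, hypoxia and glycolysis genes, Mediator, splicing and transcription machinery genes, and TGF-beta and extracellular matrix genes. They were written by hand from general knowledge, as were the gene functions in the report. Some lists share members, such as FAS and TNFRSF10B in the p53 target and apoptosis lists and TOP2A in the G2/M and topoisomerase lists. Calls of such lists are not independent. Lists were tested with camera on the same differences at a preset correlation of 0.01 between genes, and again with the correlation estimated, adjusted over the 19 lists of a comparison. BTG2, SESN2, FDXR, BBC3, RRM2B, SLFN11, TOP1MT, SERPINE1, STAT1 and TP53 were not measured here by a probe with 1 gene.

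The lists, comparisons, thresholds and the rule for naming genes were fixed before the data were examined. For 1000 nM against 0 nM the rule names the 8 genes with the largest mean rise and the 8 with the largest fall among those called and changed in the same direction in at least 80% of lines, and in the other comparisons 5 and 5. For the tissue test it names the 8 genes with the smallest p, and for each list the 4 members with the largest change, of which some are printed. CDKN1A, MDM2, TOP1 and TOP2A were always named. The myeloid and T cell markers of the mixed arrays, the line ranges and the gene families were chosen after their values were seen.

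Permutation tests used 100000 resamples with fixed seeds in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9), so that 1e-05 is the smallest p. Correlations of baseline with response, of gene length with change and of list means with each other were tested in this way over lines. The overlap of the doses was set against 100 simulations of unchanged groups with shared controls and against 100 random splits of the lines. The share of HL-60 in an array was estimated from 370 genes that differed by at least 3 log2 units between the other arrays of HL-60 and MOLT-4.

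The main test was tested on simulated data, with 200 genes changed. Each gene was given independent normal noise with the SD of its differences over lines. Correlation between genes, outlying arrays and a large number of changed genes were not simulated, so recovery in the real data may differ. A log2 change of 1 was recovered in 100% of genes at both doses and all times. A change of 0.25 was recovered in 96%, 91% and 76% at 1000 nM (2, 6 and 24 h) and in 98%, 100% and 100% at 10 nM. For the tissue test, 91.5% of genes shifted by 1.5 log2 units in leukemia lines were recovered. Alternatives tried were a fit without the pairing by line, all arrays in 1 fit with the line as a block, the mean of all probe sets of a gene, probe sets ending in _x_at left out, the 3988 genes with the lowest means left out, arrays centred on their medians, quantile normalization added, eBayes with trend and robust options, only lines with all 9 arrays, 3 lines of shared origin left out (NCI-ADR-RES, MDA-MB-435 and SNB-19), leukemia lines left out, an estimated correlation in camera, a baseline from 24 h, and lines split into 2 sets. After the data were seen, the lines HL-60 and MOLT-4, the line RPMI-8226, the CNS lines and, for the tissue test, the leukemia lines were left out in turn.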

Results

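Gene expression was measured on 525 Affymetrix oligonucleotide arrays from the 60 human tumour cell lines of the NCI-60 panel, a collection of established lines from 9 tissues that is widely used in drug testing. The cells were exposed to topotecan, a camptothecin derivative that traps topoisomerase I on DNA. Topotecan was given at 0, 10 or 1000 nM for 2, 6 or 24 h, and the 0 nM cultures were the untreated controls. Each line gave at most 1 array per dose and time, so the cell line was the replicate. The 9 groups held 59, 58 and 60 arrays at 0 nM (2, 6 and 24 h), 59, 57 and 59 arrays at 10 nM, and 57, 58 and 58 arrays at 1000 nM. There were 6 breast, 6 central nervous system (CNS), 7 colon, 6 leukemia, 9 lung, 9 melanoma, 7 ovarian, 2 prostate and 8 renal lines. Values are log2 expression levels as deposited, and each change below is the treated minus the untreated array of the same line, averaged over lines ± SD. In total, 11963 genes were tested, and the number of arrays limited the precision of every value. "Rose" and "fell" mean an adjusted p under 0.05 in limma, and "called" means also a mean change of at least 1.5-fold.

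The 6 haematopoietic markers averaged 9.82 ± 1.13 in the 6 leukemia lines and 4.23 to 4.97 in the other tissues. The 5 measured melanocytic markers averaged 9.91 ± 2.61 in the 9 melanoma lines and 4.0 to 4.54 in the other tissues, and the lowest melanoma line stood at 4.19, within the range of the other tissues. Epithelial markers were highest in colon lines (11.12 ± 0.61, n = 7) and mesenchymal markers in CNS lines (11.24 ± 0.84, n = 6). All but 3 of the 525 arrays correlated best with another array of the same line. The HL-60 array at 0 nM and 2 h and the MOLT-4 array at 1000 nM and 2 h, both from leukemia lines, correlated best with each other (r = 0.993 across genes). Both carried markers of both lines. MPO, a myeloid granule enzyme, stood at 11.98 and 11.99 in these arrays, against 12.37 in the other HL-60 arrays and 3.77 in the other MOLT-4 arrays. CD3D, a T cell receptor component, stood at 10.54 and 10.70, against 4.63 and 11.47. The remaining array, OVCAR-8 at 1000 nM and 24 h, correlated best with NCI-ADR-RES (r = 0.980), a line of the same origin. The counts of genes in comparisons that use the HL-60 and MOLT-4 arrays at 2 h are also given without both lines. The values of named genes, lists, the dose overlap, response size, gene length and gene families at 2 h include them.

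The first comparison asked which genes changed within 2 h of 1000 nM topotecan (n = 56 lines). FOS, a subunit of the AP-1 transcription factor, rose by 1.73 ± 0.66 on the log2 scale in 56 of 56 lines, and JUNB, another AP-1 subunit, rose by 1.08 ± 0.64 in 56 of 56. RSRP1 (1.56 ± 0.43), RGS2, a regulator of G protein signalling (1.48 ± 0.76), TNFSF9, a T cell co-stimulatory ligand (1.06 ± 0.53), ID2, an inhibitor of helix-loop-helix factors (1.04 ± 0.73), TOB1, an antiproliferative protein (1.02 ± 0.55), and GADD45B, a stress sensor (0.97 ± 0.82), rose as well. More genes were called lower than higher. JMJD1C, of the jumonji demethylase family, fell by 1.69 ± 0.70 and MSL2, a ubiquitin ligase of a histone acetyltransferase complex, fell by 1.61 ± 0.57, each in 56 of 56 lines. ZNF430, a zinc finger protein (-1.28 ± 0.48), TIPARP, a mono-ADP-ribosyltransferase (-1.27 ± 0.97), ARID5B, a DNA-binding protein (-1.09 ± 0.59), and RLF, a zinc finger protein (-1.07 ± 0.41), also fell. The kinase gene DYRK1A (-1.17 ± 0.52) and CNOT4, of the deadenylase complex (-1.16 ± 0.73), fell by their brightest probes, but other probes of these genes moved by only 0.00 and -0.07. Limma's adjusted p for these 16 genes lay between 6.4e-32 and 1.5e-11.

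At 2 h, 18 of 37 measured immediate early and AP-1 genes rose, 6 fell and 13 did not pass (18 and 7 when adjusted over the list alone; camera adjusted p = 0.000121). That list's adjusted p = 0.204 with an estimated correlation. IER5, an immediate early response gene, rose by 0.96 ± 0.53. Of the 39 measured members of the hand-written list of genes over 200 kb long, 24 fell and 1 rose (25 and 1 adjusted over the list alone; camera adjusted p = 1.26e-08), among them the phosphodiesterase gene PDE4D (-0.71 ± 0.50, other probes up to -0.05) and the ataxin gene ATXN1 (-0.47 ± 0.53). Genes of Mediator, splicing and the transcription machinery fell in 13 of 23 cases and rose in 1 (13 and 2 adjusted over the list alone; camera adjusted p = 0.000121). They included CCNT2, a cyclin of the elongation kinase P-TEFb (-0.98 ± 0.46, other probes up to -0.13), and the Mediator subunit gene MED17 (-0.27 ± 0.22). Of 40 genes for G2/M and mitosis, 20 fell and 1 rose, both over all genes and adjusted over the list alone, with camera adjusted p = 0.000227 and adjusted p = 0.283 with an estimated correlation. The mitotic kinesin genes KIF23 (-0.39 ± 0.20) and KIF11 (-0.33 ± 0.20) fell most. G1/S and DNA replication genes fell in 14 of 35 cases and rose in 1, also over the list alone (camera adjusted p = 0.00296). The latter list's adjusted p = 0.246 with an estimated correlation. Heat shock genes rose in 7 of 11 cases (7 over the list alone; camera adjusted p = 0.0175; adjusted p = 0.0619 with an estimated correlation), among them the co-chaperone gene DNAJB1 (0.24 ± 0.22).

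No other list passed camera at 2 h. Of 31 p53 targets, 6 rose and 8 fell (6 and 9 over the list alone; camera adjusted p = 0.471), with GDF15, a stress cytokine, at 0.40 ± 0.58 and PPM1D, a phosphatase that acts on p53, at -0.71 ± 0.59. The mean of that list was -0.03, its median 0.01 and its camera direction down. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 0.25 ± 0.44 in 46 of 56 lines. MDM2, the ubiquitin ligase of p53, did not pass (0.08 ± 0.48), and its 5 probes ranged from -0.19 to 0.08. TOP1, which encodes the target of the drug, fell by 0.06 ± 0.14 in 35 of 56 lines and TOP2A, topoisomerase II alpha, fell by 0.11 ± 0.33. The apoptosis regulator PMAIP1 rose by 0.75 ± 0.56, while the checkpoint and repair genes BARD1 (-0.68 ± 0.41) and WEE1 (-0.53 ± 0.29) fell. In limma, 145 genes were called (32 higher, 113 lower), and 1924 genes rose and 2025 fell at any fold. Without HL-60 and MOLT-4, 146 genes were called. Of 60 called genes with several probes, 49 had all probes in 1 direction, but 31 had a probe below 0.5 of the log2 minimum for a call.

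At 6 h of 1000 nM topotecan (n = 57 lines), ATF3, a stress-induced transcription factor, rose by 2.94 ± 1.63 in 56 of 57 lines, FOS by 2.23 ± 1.66 in 57, JUNB by 1.86 ± 1.13 in 57 and GADD45B by 1.76 ± 0.95 in 57. EGR1, an immediate early zinc finger factor, rose by 1.71 ± 1.90 in 46 lines, and TNFSF9 (1.69 ± 0.88), RGS2 (1.68 ± 0.92) and RSRP1 (1.68 ± 0.49) rose too. The falling genes included NCOA2, a nuclear receptor coactivator (-2.21 ± 0.67 in 56 lines), TRIO, a guanine nucleotide exchange factor (-1.98 ± 0.84), MED13L, a Mediator subunit (-1.98 ± 0.66), TCF7L2, a transcription factor of Wnt signalling (-1.96 ± 0.71), and ATXN1 (-1.92 ± 0.88). PLEKHA5 (-1.86 ± 0.72), RAPGEF2, an exchange factor for Rap (-1.82 ± 0.61), and ZMIZ1, a transcriptional coregulator (-1.82 ± 0.65), fell as well. Their probes differed: other probes reached -0.17 for NCOA2, 0.09 for TRIO, 0.01 for PLEKHA5 and -0.05 for RAPGEF2. Limma's adjusted p for these 16 genes was at most 8.9e-09.

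**Figure D1:**
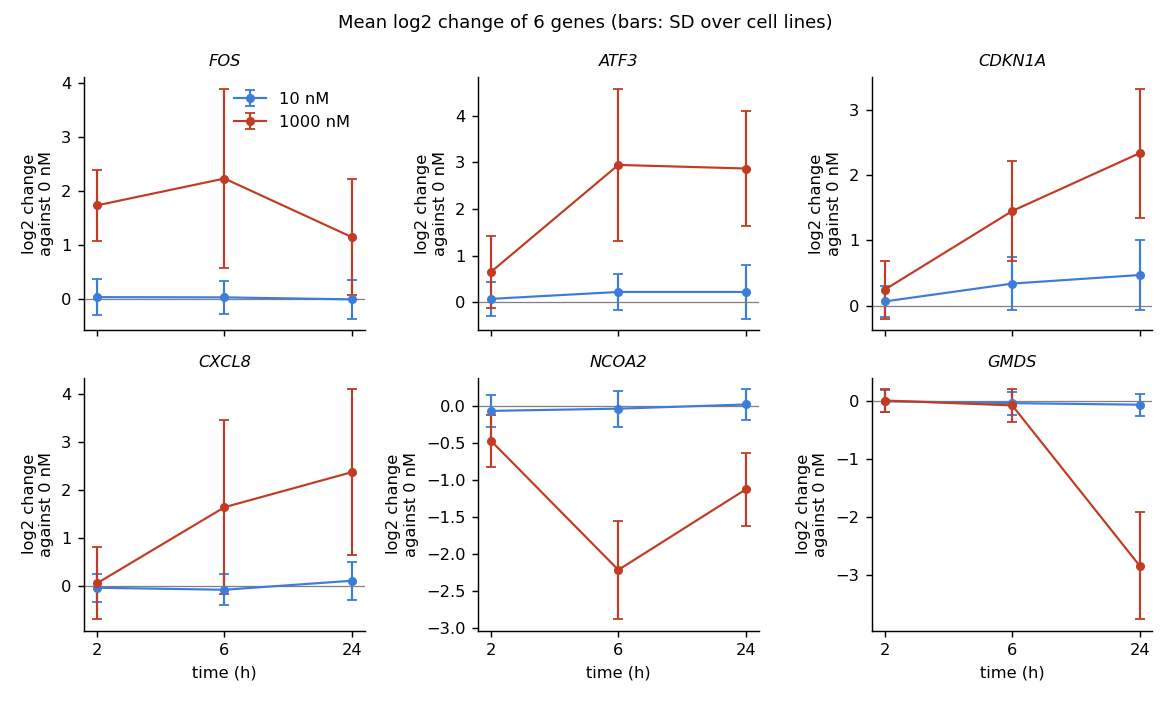
Mean log2 change against 0 nM (vertical axes, 1 panel per gene) at 2, 6 and 24 h (horizontal axis) for 10 nM (blue) and 1000 nM (red), with bars for the SD over 56 to 59 cell lines. At 1000 nM FOS stood highest at 6 h (2.23), CDKN1A at 24 h (2.33), NCOA2 lowest at 6 h (-2.21) and GMDS lowest at 24 h (-2.85).

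Cell cycle genes of G2/M and mitosis fell in 39 of 40 cases at 6 h, with none higher, both over all genes and adjusted over the list alone (mean -0.64, camera adjusted p = 1.94e-25, adjusted p = 0.00923 with an estimated correlation). The mitotic genes PSRC1 (-1.42 ± 0.56), CENPE (-1.37 ± 0.60), KIF11 (-1.31 ± 0.38) and ASPM (-1.19 ± 0.32) led them. Among the 35 genes for G1/S and replication, 17 rose and 11 fell (the same numbers over the list alone; camera adjusted p = 0.536). The cyclin E genes CCNE1 (1.16 ± 0.54) and CCNE2 (0.66 ± 0.44) rose, whereas GINS1, of the replicative helicase (-0.60 ± 0.26), and RFC3, of the clamp loader (-0.58 ± 0.34), fell. Of the listed long genes, 36 of 39 fell and none rose, over all genes and over the list alone (mean -0.71, camera adjusted p = 1.12e-15, adjusted p = 0.00596 with an estimated correlation), with FNDC3B at -1.80 ± 0.76 and EXT1, a heparan sulfate polymerase gene, at -1.54 ± 0.66. DNA repair and checkpoint genes fell in 25 of 42 cases and rose in 11, also over the list alone, with camera adjusted p = 0.00163 and adjusted p = 0.122 with an estimated correlation. The end-joining gene XRCC4 fell by 1.30 ± 0.52 (other probes up to 0.03), BARD1 by 1.08 ± 0.47, and the RecQ helicase genes WRN by 1.00 ± 0.42 and BLM by 0.98 ± 0.44.

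Immediate early and AP-1 genes rose in 35 of 37 cases at 6 h and fell in 1 (the same over the list alone; mean 0.87; camera adjusted p = 1.02e-08; adjusted p = 0.179 with an estimated correlation). NF-kB targets rose in 21 of 22 cases and fell in 1 (the same over the list alone; mean 0.70; camera adjusted p = 0.00101; adjusted p = 0.401 with an estimated correlation). They included the chemokine genes CXCL8 (1.64 ± 1.81) and CXCL2 (1.54 ± 1.74) and the feedback inhibitors TNFAIP3 (1.47 ± 1.28) and NFKBIA (1.38 ± 0.84). Of the p53 targets, 23 of 31 rose and 2 fell (the same over the list alone; mean 0.36; camera adjusted p = 0.00520; adjusted p = 0.415 with an estimated correlation). CDKN1A rose by 1.45 ± 0.76 in 56 of 57 lines, GADD45A, a growth arrest gene, by 1.34 ± 0.92, and PLK3, a stress kinase gene, by 1.17 ± 0.88. The stress and unfolded protein response list rose in 15 of 19 cases and fell in 3, over all genes and the list alone (mean 0.42; camera adjusted p = 0.00355; adjusted p = 0.263 with an estimated correlation), with DNAJB9, a chaperone of the endoplasmic reticulum, at 1.23 ± 0.45 and CHAC1, a glutathione-degrading enzyme, at 1.21 ± 0.93.

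Smaller mean changes at 6 h were seen in other lists. Histone genes rose in 18 of 26 cases and fell in 3 (the same over the list alone; mean 0.22; camera adjusted p = 0.0276; adjusted p = 0.415 with an estimated correlation), led by H2AJ (0.89 ± 0.70) and H2BC21 (0.79 ± 0.68). Cholesterol synthesis genes rose in 10 of 13 cases and fell in 1 (the same over the list alone; mean 0.17; camera adjusted p = 0.0168; adjusted p = 0.179 with an estimated correlation). Heat shock genes rose in 8 of 11 cases and fell in 1 (9 and 1 over the list alone; mean 0.16; camera adjusted p = 0.0384; adjusted p = 0.263 with an estimated correlation). Ribosomal protein genes rose in 16 of 32 cases, also over the list alone (mean 0.04; camera adjusted p = 0.0480; adjusted p = 0.415 with an estimated correlation). Topoisomerases and drug handling genes fell in 6 of 12 cases and rose in 2, also over the list alone (mean -0.17; camera adjusted p = 0.0384; adjusted p = 0.179 with an estimated correlation). TDP1, which removes topoisomerase I adducts, fell by 0.76 ± 0.36, the transporter gene ABCC1 by 0.57 ± 0.37, TOP2A by 0.50 ± 0.29 and TOP1 by 0.31 ± 0.18 in 57 of 57 lines. MDM2 rose by 0.56 ± 0.97 in 37 of 57 lines by its brightest probe, but its 5 probes ranged from -0.28 to 0.56. Without probes prone to cross-hybridisation MDM2 stood at -0.28.

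Interferon genes did not pass camera at 6 h (adjusted p = 0.116), with 10 of 24 higher and 2 lower, and IRF7, an interferon regulatory factor, at 1.04 ± 0.51. Among the transcription machinery genes 10 rose and 10 fell, with HEXIM1, an inhibitor of P-TEFb, at 1.26 ± 0.56 and MED13 at -0.83 ± 0.37. The mean of that list was 0.05 while its camera direction was down (adjusted p = 0.546). In limma, 911 genes were called at 6 h, 258 higher and 653 lower (28.3% higher). With each array centred on its median, the split was 335 higher and 533 lower of 868 (38.6% higher). At any fold 4498 genes rose and 2977 fell, and 352 of 438 called genes with several probes had all of them in 1 direction, but 201 had a probe below 0.5 of the log2 minimum. RPMI-8226, a line labelled as leukemia, stood apart at this dose and time. Its change correlated with the mean change of the other lines at r = 0.0424 across genes, against a median of 0.711 over lines and 0.470 in the next lowest line. It had 46 genes changed at least 2-fold, against 507 ± 183 over lines, a mean change of -0.26 in the G2/M list and -0.05 in the long gene list. Without RPMI-8226, 935 genes were called, and 910 of the 911 genes were among them.

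After 24 h of 1000 nM topotecan (n = 58 lines), ATF3 rose by 2.87 ± 1.23, CXCL8 by 2.37 ± 1.72, CDKN1A by 2.33 ± 0.99 (58 of 58 lines) and GADD45A by 1.92 ± 1.14. TP53I3, an oxidoreductase gene controlled by p53 (1.73 ± 1.23), PPP1R15A, a phosphatase regulator of the stress response (1.73 ± 0.90), HBEGF, a growth factor (1.66 ± 0.82, other probes down to -0.01), and DLX2, a homeobox gene (1.63 ± 1.07), also rose. The largest falls were in GMDS, an enzyme of GDP-fucose synthesis (-2.85 ± 0.93), VPS13B, a vesicle transport protein (-2.75 ± 0.79), AGAP1, a GTPase activator (-2.58 ± 0.87), SMYD3, a methyltransferase (-2.56 ± 0.67), and LPP, a focal adhesion protein (-2.47 ± 0.88). TBC1D5, a Rab GTPase activator (-2.41 ± 0.62), DPYD, the enzyme that degrades uracil (-2.38 ± 1.59), and FAF1 (-2.25 ± 0.68) fell as well. A second probe of VPS13B stood at 0.02 and one of LPP at 0.21. Limma's adjusted p for these 16 genes was at most 1.5e-14, and each changed in its direction in at least 53 lines.

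Of 31 p53 targets, 27 rose and 2 fell at 24 h, over all genes and over the list alone (mean 0.70; camera adjusted p = 5.01e-07; adjusted p = 0.347 with an estimated correlation). GDF15 was at 1.55 ± 1.56, although its second probe stood at 0.09, and MDM2 rose by 1.18 ± 1.32 in 51 lines with probes from 0.07 to 1.18. Interferon response genes rose in 23 of 24 cases, also over the list alone (mean 0.64; camera adjusted p = 1.11e-06; adjusted p = 0.336 with an estimated correlation). They included IRF7 (1.45 ± 0.80), the ubiquitin-like ISG15 (1.27 ± 0.96), IFI6 (1.08 ± 0.78) and the antiviral GTPase gene MX1 (0.86 ± 0.94). NF-kB targets rose in 19 of 22 cases, or 20 over the list alone (mean 0.75; camera adjusted p = 3.28e-06; adjusted p = 0.305 with an estimated correlation), with RELB, an NF-kB subunit, at 1.12 ± 0.73 and the chemokine gene CCL20 at 1.12 ± 1.54. Immediate early and AP-1 genes rose in 33 of 37 cases and fell in 2 (the same over the list alone; mean 0.66; camera adjusted p = 5.96e-09; adjusted p = 0.0283 with an estimated correlation), among them KLF4 (1.45 ± 0.97), MAFF (1.41 ± 1.11) and the antiproliferative gene BTG1 (1.37 ± 0.71). Apoptosis regulators rose in 18 of 25 cases and fell in 3 (the same over the list alone; mean 0.29; camera adjusted p = 0.00535; adjusted p = 0.102 with an estimated correlation). The BH3-only gene PMAIP1 rose by 1.56 ± 0.84 and the death receptor genes FAS by 0.94 ± 1.03 and TNFRSF10B by 0.77 ± 0.64. FAS and TNFRSF10B are also in the p53 target list. Stress and unfolded protein response genes rose in 13 of 19 cases and fell in 3 (14 and 3 over the list alone; mean 0.41; camera adjusted p = 0.0251; adjusted p = 0.488 with an estimated correlation), with DDIT3, a stress-induced factor, at 1.57 ± 1.09 and the cystine transporter gene SLC7A11 at -0.80 ± 1.11.

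**Figure D2:**
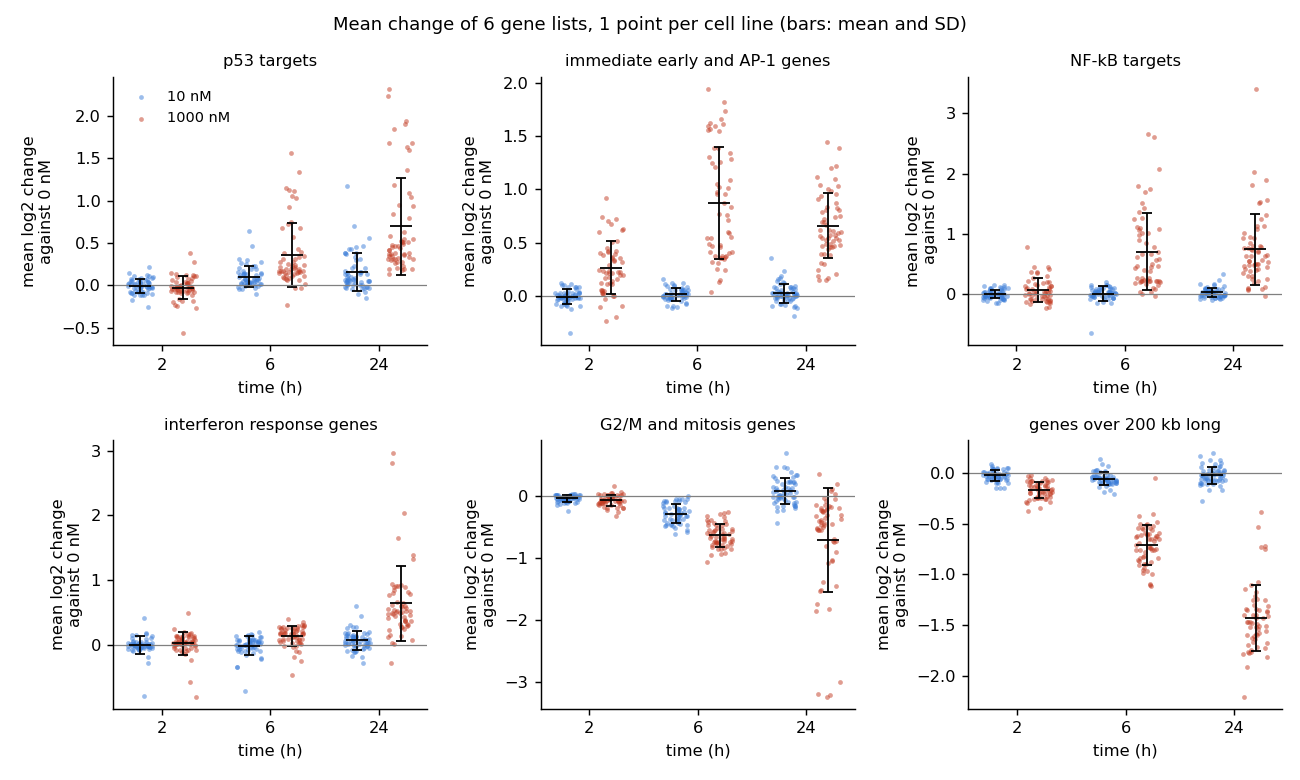
Mean log2 change against 0 nM of 6 gene lists (vertical axes) at 2, 6 and 24 h (horizontal axes), 1 point per cell line, blue for 10 nM and red for 1000 nM, with bars for the mean and SD. At 1000 nM and 24 h the long gene list averaged -1.43 ± 0.33 and the p53 target list 0.70 ± 0.58, while the G2/M list averaged -0.29 ± 0.16 at 10 nM and 6 h.

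All 39 measured members of the hand-written long gene list fell at 24 h, over all genes and over the list alone (mean -1.43, 0 of 58 lines above 0; camera adjusted p = 1.57e-34; adjusted p = 3.17e-05 with an estimated correlation). The list does not stand for all long genes, since the mean over lines of the median change of the 718 measured genes of 200 to 500 kb was -0.06, -0.20 and -0.27 at 2, 6 and 24 h, and that of the 214 over 500 kb was -0.04, -0.10 and -0.16. In the G2/M list 33 of 40 genes fell and none rose, or 34 over the list alone (mean -0.72; camera adjusted p = 1.34e-12; adjusted p = 0.347 with an estimated correlation). The mitotic kinase gene PLK1 fell by 1.74 ± 0.99, PSRC1 by 1.43 ± 0.78, CDC20, an activator of the anaphase-promoting complex, by 1.27 ± 0.94 and TOP2A by 0.74 ± 0.99. G1/S and replication genes went both ways, with 10 higher and 4 lower of 35 (10 and 3 over the list alone; camera adjusted p = 0.837). Their mean per line had an SD of 0.88 around 0.07, from -2.11 in LOX to 2.25 in SNB-75. POLA1, the catalytic subunit of DNA polymerase alpha, fell by 1.32 ± 0.89, whereas CCNE1 rose by 0.68 ± 0.99. TGF-beta and extracellular matrix genes fell in 10 of 19 cases and rose in 1 (11 and 1 over the list alone; mean -0.24; camera adjusted p = 0.0150; adjusted p = 0.402 with an estimated correlation), with the laminin gene LAMC1 at -0.67 ± 0.58 and the collagen gene COL4A2 at -0.65 ± 0.86. Cholesterol synthesis genes fell in 7 of 13 cases and rose in 1 (7 and 2 over the list alone; mean -0.17; camera adjusted p = 0.0426; adjusted p = 0.563 with an estimated correlation), led by INSIG1, a sterol sensor (-0.60 ± 0.77). Hypoxia and glycolysis genes fell in 8 of 16 cases and rose in 3 (8 and 4 over the list alone; mean -0.08; camera adjusted p = 0.0377; adjusted p = 0.402 with an estimated correlation). The hexokinase gene HK2 fell by 0.59 ± 0.55, while ADM, a vasodilator peptide gene, rose by 0.78 ± 0.91.

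The other lists did not pass camera at 24 h. Transcription machinery genes rose in 12 of 23 cases and fell in 8 (adjusted p = 0.315), with the splicing kinase gene CLK1 at 1.08 ± 0.67. DNA repair genes rose in 11 of 42 cases and fell in 10 (adjusted p = 0.211), with XRCC4 at -1.19 ± 0.44 (other probes up to -0.02) and PRKDC, the DNA-dependent protein kinase gene, at -0.72 ± 0.37. Histone genes rose in 8 of 26 cases and fell in 3 (adjusted p = 0.971), and heat shock genes rose in 4 of 11 and fell in 3 (adjusted p = 0.837). Both had a mean above 0 (0.03 and 0.06) and a camera direction of down. Nucleolar genes rose in 8 of 17 cases and fell in 3 (adjusted p = 0.384), ribosomal protein genes rose in 11 of 32 and fell in 4 (adjusted p = 0.291), and topoisomerases and drug handling genes rose in 6 of 12 and fell in 4 (adjusted p = 0.571). The topoisomerase list had a mean of -0.09, a median of 0.11 and a camera direction of down. Within it TDP1 fell by 0.82 ± 0.41 and ABCC1 by 0.78 ± 0.43, while TOP1 rose by 0.21 ± 0.29 in 44 of 58 lines. In limma 959 genes were called, 431 higher and 528 lower, and 3676 rose and 2644 fell at any fold. Of 430 called genes with several probes, 372 had all of them in 1 direction, but 198 had a probe below 0.5 of the log2 minimum.

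**Figure D3:**
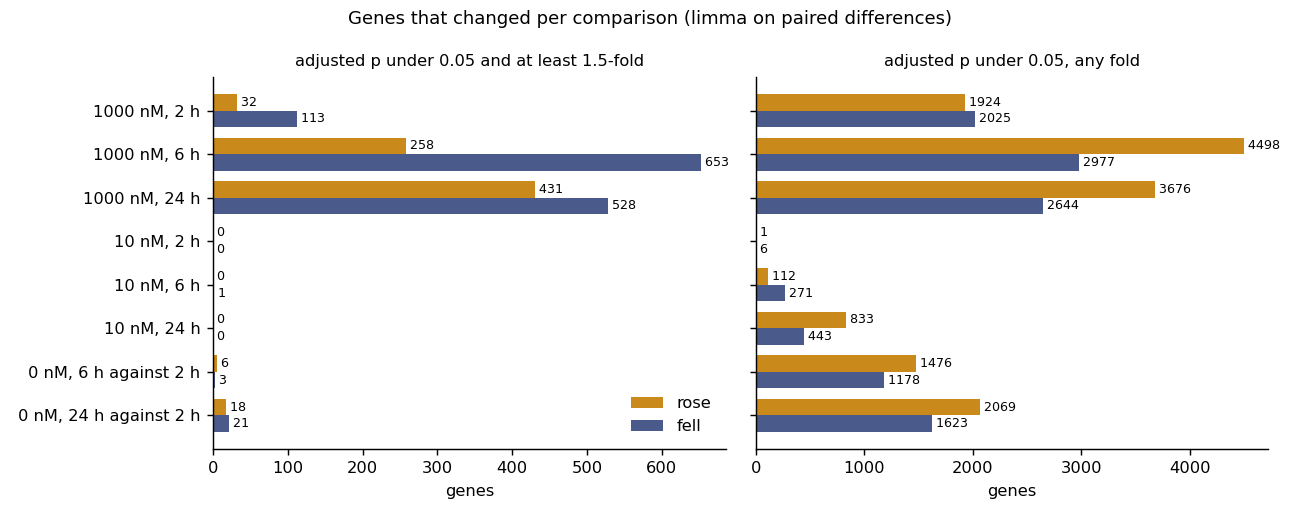
Number of genes (horizontal axes) that rose or fell in each comparison (vertical axis), on the left with an adjusted p under 0.05 and at least 1.5-fold and on the right at any fold. The called counts for 1000 nM were 32 and 113 at 2 h, 258 and 653 at 6 h, and 431 and 528 at 24 h, against at most 1 for 10 nM against 0 nM.

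Across all lists at both doses, 28 list tests lost their call with an estimated correlation. The 114 list tests include those that were not calls and had none to lose. So 28 of 114 is not the share of calls that were lost. At 1000 nM the calls that held were the long gene list at 2, 6 and 24 h, the transcription machinery genes at 2 h, the G2/M genes at 6 h and the immediate early genes at 24 h. With the genes of lowest mean left out, 11 list calls were lost: at 1000 nM heat shock, ribosomal protein and topoisomerase genes at 6 h and apoptosis, stress response, cholesterol, hypoxia and TGF-beta genes at 24 h, and at 10 nM histone and topoisomerase genes at 6 h and stress response genes at 24 h. Quantile normalization ended 5, all at 1000 nM: heat shock genes at 2 and 6 h, ribosomal protein genes at 6 h, and cholesterol and hypoxia genes at 24 h. The lists not yet given were far from the threshold or mixed. At 2 h NF-kB targets rose in 7 of 22 cases and fell in 1 (camera adjusted p = 0.246). The hypoxia list had a mean of 0.01 but a camera direction of down at 2 h, and at 6 h a mean of 0.07, a median of -0.02 and a camera direction of up. The nucleolar list at 2 h had a mean of -0.03 and a median of 0.01.

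The comparison of 10 nM with 0 nM asked what a 100-fold lower dose did. Mitotic genes were lower at 6 h, p53 targets were higher at 6 and 24 h, and nearly all changes were under 1.5-fold. At 6 h (n = 56 lines) PSRC1 fell by 0.65 ± 0.36 in 55 lines, CENPE by 0.53 ± 0.31 in 55, PLK1 by 0.53 ± 0.38 in 51, the mitotic kinase gene AURKA by 0.51 ± 0.29 in 56 and TOP2A by 0.26 ± 0.20 in 51. CDKN1A rose by 0.34 ± 0.40 in 45 of 56 lines and CCNE2 by 0.28 ± 0.27 in 53. At 24 h (n = 59 lines) CDKN1A rose by 0.47 ± 0.54 in 48 lines, FAS by 0.29 ± 0.49 in 43 and TP53I3 by 0.25 ± 0.34 in 51. The mitotic genes NEK2 (0.26 ± 0.27) and CDK1 (0.23 ± 0.23) stood above the untreated level at 24 h. Limma's adjusted p was at most 0.000745 for these values. MDM2 did not pass at 10 nM by its brightest probe (0.00 ± 0.32, 0.08 ± 0.42 and 0.15 ± 0.64 at 2, 6 and 24 h). At 24 h its 5 probes ranged from -0.045 to 0.281. TOP2A, lower at 6 h, was higher at 24 h (0.14 ± 0.25 in 41 lines). TOP1 stood at -0.02 ± 0.13, -0.06 ± 0.12 and 0.07 ± 0.12, of which the first did not pass.

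At 10 nM and 2 h (n = 58 lines), 3 of 40 G2/M genes fell over all genes and 21 fell adjusted over the list alone (mean -0.05; camera adjusted p = 1.40e-26; adjusted p = 6.71e-06 with an estimated correlation). MKI67, the proliferation antigen Ki-67, fell by 0.09 ± 0.12. At 6 h 39 of the 40 fell, or 40 over the list alone (mean -0.29, 0 of 56 lines above 0; adjusted p = 5.37e-09 with an estimated correlation). At 24 h 14 rose and none fell, or 15 over the list alone (mean 0.07; camera adjusted p = 1.96e-07; adjusted p = 0.441 with an estimated correlation). Of the p53 targets, 15 of 31 rose at 6 h (18 over the list alone; camera adjusted p = 7.25e-20; adjusted p = 0.000494 with an estimated correlation) and 22 at 24 h (22 over the list alone; camera adjusted p = 3.04e-14; adjusted p = 0.0363 with an estimated correlation). G1/S and replication genes rose in 17 of 35 cases at 6 h (24 over the list alone; camera adjusted p = 2.23e-23; adjusted p = 0.000383 with an estimated correlation), among them CDC6, a licensing factor (0.18 ± 0.19). At 24 h 11 of them fell and 1 rose (camera adjusted p = 9.51e-05; adjusted p = 0.441 with an estimated correlation), with the helicase gene MCM6 at -0.29 ± 0.31. Histone genes fell in 1 of 26 cases at 6 h (adjusted p = 0.00826 with an estimated correlation) and in 10 at 24 h (12 over the list alone; mean -0.11; adjusted p = 0.00780 with an estimated correlation), with the linker histone genes H1-10 at -0.31 ± 0.34 and H1-2 at -0.30 ± 0.37. Members of the long gene list fell in 7 of 39 cases at 6 h (13 over the list alone; mean -0.06; adjusted p = 0.000109 with an estimated correlation), with NAV2 at -0.19 ± 0.34. They fell in 3 cases at 24 h (5 over the list alone; camera adjusted p = 0.00401; adjusted p = 0.263 with an estimated correlation). At 2 h none passed in limma, or 2 over the list alone, with a mean of -0.03 and adjusted p = 0.00574 with an estimated correlation.

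Nucleolar genes fell in 7 of 17 cases at 10 nM and 24 h (8 over the list alone; mean -0.05; adjusted p = 0.0199 with an estimated correlation), and apoptosis regulators rose in 6 of 25 (9 over the list alone; mean 0.06; adjusted p = 0.0363 with an estimated correlation). Interferon genes rose in 4 of 24 cases (4 over the list alone; mean 0.07; camera adjusted p = 0.00165; adjusted p = 0.263 with an estimated correlation) and stress response genes in 2 of 19 (6 over the list alone; mean 0.07; camera adjusted p = 0.0218; adjusted p = 0.450 with an estimated correlation). Topoisomerases and drug handling genes fell in 3 of 12 cases at 6 h (3 over the list alone; adjusted p = 0.0217 with an estimated correlation), including TDP1 (-0.16 ± 0.19). Heat shock genes passed camera at 2 h with a mean of 0.03 (adjusted p = 0.000909 with an estimated correlation), although no member passed alone. The other lists at 10 nM did not pass camera. The mean, the median and the camera direction differed in sign for p53 targets, immediate early, G1/S, repair and cholesterol genes at 2 h, repair and apoptosis genes at 6 h, and heat shock and transcription machinery genes at 24 h, none of which were calls. In limma the called counts were 0, 1 and 0 at 2, 6 and 24 h, with 784, 1545 and 2727 genes at an unadjusted p under 0.05. The 1 called gene was PSRC1. At any fold, 1 gene rose and 6 fell at 2 h, 112 and 271 at 6 h, and 833 and 443 at 24 h. A fit without the pairing by line (no replicate block) passed 0 genes at each time. With all arrays in 1 fit and the line as the replicate block, 0, 37 and 134 genes passed at 2, 6 and 24 h in place of 7, 383 and 1276. Without HL-60 and MOLT-4, 8 genes passed at 2 h in place of 7. HL-60 had 685 genes changed at least 2-fold at 10 nM and 2 h, against a median of 10.5 over lines. Its untreated array at 2 h is the mixed one, with an estimated HL-60 share of 54.5%, against 106% in its 10 nM array. That count can therefore not be read as an effect of the drug.

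The direct comparison of 1000 nM with 10 nM tested the difference between the doses. At 2 h (n = 57 lines) FOS (1.70 ± 0.61), RSRP1 (1.49 ± 0.40), RGS2 (1.47 ± 0.72), JUNB (1.07 ± 0.60) and ID2 (1.02 ± 0.77) were higher at 1000 nM, and MSL2 (-1.54 ± 0.59), JMJD1C (-1.53 ± 0.71), TIPARP (-1.32 ± 0.96), ZNF430 (-1.21 ± 0.45) and CNOT4 (-1.15 ± 0.64, other probes up to 0.01) were lower. At 6 h (n = 56 lines) ATF3 was higher by 2.68 ± 1.62, FOS by 2.22 ± 1.66, CXCL8 by 1.77 ± 1.85, JUNB by 1.76 ± 1.06 and GADD45B by 1.70 ± 0.95. NCOA2 (-2.15 ± 0.69), TCF7L2 (-1.90 ± 0.69), TRIO (-1.86 ± 0.78), MED13L (-1.86 ± 0.64) and RAPGEF2 (-1.80 ± 0.58) were lower. At 24 h (n = 57 lines) the largest differences were in ATF3 (2.59 ± 1.23), CXCL8 (2.25 ± 1.75), CDKN1A (1.83 ± 0.85), GADD45A (1.68 ± 1.08) and PPP1R15A (1.63 ± 0.96), and in VPS13B (-2.79 ± 0.77), GMDS (-2.78 ± 0.91), SMYD3 (-2.54 ± 0.65), AGAP1 (-2.52 ± 0.90) and LPP (-2.48 ± 0.88). TOP2A did not differ between the doses at 2 h by limma (-0.02 ± 0.31, adjusted p = 0.71), and it was lower at 1000 nM at 6 h (-0.26 ± 0.26) and 24 h (-0.89 ± 0.95 in 53 lines). TOP1 was lower at 1000 nM at 2 h (-0.06 ± 0.12) and 6 h (-0.25 ± 0.17) and higher at 24 h (0.15 ± 0.29). MDM2 was at 0.07 ± 0.46 at 2 h, which did not pass, 0.47 ± 0.90 at 6 h and 1.04 ± 1.19 at 24 h. Its probes ranged from -0.34 to 0.47 at 6 h. Limma called 117 genes at 2 h (26 higher, 91 lower), 806 at 6 h (219 and 587) and 826 at 24 h (306 and 520). At 6 h the share higher was 27.2%, and it was 38.8% with centred arrays (296 and 466 of 762). Without HL-60 and MOLT-4 the count at 2 h was 121, and without RPMI-8226 the count at 6 h was 830.

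The mean changes at 10 and 1000 nM were also correlated across genes, which are not independent replicates, and both comparisons used the same untreated arrays. The correlation was 0.340, 0.407 and 0.356 at 2, 6 and 24 h (n = 56, 55 and 57 lines with all 3 arrays). Simulated unchanged groups against shared controls gave 0.50 at each time. The covariance was 0.00179, 0.00612 and 0.00662, against simulated values of 0.000573, 0.000524 and 0.000574, so the differences were 0.00121, 0.00560 and 0.00605. With the lines split so that no control array was shared, the correlation was 0.151, 0.302 and 0.266. Genes that rose at both doses numbered 0, 81 and 481, against 0.161, 40.2 and 222 for independent lists. Genes that fell at both doses numbered 6 at 2 h and 207 at 6 h, against 1.02 and 60.7. At 24 h 732 genes went the same way at both doses, of which 481 rose and the others fell (222 and 90.3 for independent lists). The shared untreated arrays make independent lists a loose reference. Simulated unchanged groups with shared controls had 0 genes that rose or fell at both doses, but no gene was changed at either dose in them. They cannot show how many shared calls the untreated arrays add beside a real 1000 nM effect. With no control array shared, a mean of 20.1 genes rose and 93.8 fell at both doses at 6 h (8.23 and 24.4 for independent lists), and 80.8 and 38.4 at 24 h (31.3 and 13.3). With all lines, 122 genes went in opposite directions at 24 h, of which 85 fell at 1000 nM and rose at 10 nM.

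Differences in the 1000 nM effect between times were tested in lines with all arrays concerned. Between 2 and 6 h (n = 53 lines) the effect on ATF3 rose by 2.30 ± 1.65, on TIPARP by 1.76 ± 1.08, on TNFAIP3 by 1.62 ± 1.25, on CXCL8 by 1.57 ± 1.70 and on TRIM13, a ubiquitin ligase, by 1.5 ± 0.58. NCOA2 (-1.77 ± 0.70), TRIO (-1.64 ± 0.76), MED13L (-1.56 ± 0.71), ATXN1 (-1.46 ± 0.74) and EHBP1 (-1.45 ± 0.76) moved down. From 6 to 24 h (n = 55 lines) the effect on HDAC9, a histone deacetylase, rose by 1.75 ± 1.27, on PPP4R3B, a phosphatase subunit, by 1.47 ± 0.90, on TP53I3 by 1.42 ± 1.11, on KDM6A, a histone demethylase, by 1.38 ± 0.75 and on ARID4B by 1.36 ± 0.65 (a second ARID4B probe stood at -0.14). GMDS (-2.79 ± 0.98), SMYD3 (-2.35 ± 0.76), TBC1D5 (-2.26 ± 0.78), LPP (-2.14 ± 0.92) and DPYD (-2.09 ± 1.60) moved down. The effect on CDKN1A rose by 1.2 ± 0.72 and then by 0.91 ± 0.76. On TOP1 it fell by 0.23 ± 0.21 and then rose by 0.52 ± 0.31 in 54 of 55 lines. TOP2A moved by -0.36 ± 0.39 and then by -0.29 ± 1.04, which did not pass. MDM2 moved by 0.45 ± 0.91, with probes from -0.20 to 0.45, and by 0.66 ± 0.68. Limma called 632 genes between 2 and 6 h (268 up, 364 down) and 726 between 6 and 24 h (484 up, 242 down). The share up of the latter was 66.7%, and it was 49.3% with centred arrays (333 and 342 of 675) and 56.0% with quantile normalization (376 and 296 of 672). Without HL-60 and MOLT-4 the first count was 639, and without RPMI-8226 the counts were 658 and 743.

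Untreated arrays showed what time in culture did without drug. From 2 to 6 h (n = 57 lines) the zinc finger gene ZNF322 rose by 0.82 ± 0.41, RNF111, a ubiquitin ligase, by 0.76 ± 0.33, TOB2 by 0.68 ± 0.37, DDIT4, an inhibitor of mTOR signalling, by 0.66 ± 0.65 and ZNF623 by 0.63 ± 0.44. ATF3 (-0.91 ± 0.82), KLF11 (-0.75 ± 0.57) and the co-chaperone gene CHORDC1 (-0.70 ± 0.34) fell. From 2 to 24 h (n = 59 lines) DDIT4 rose by 1.33 ± 1.02, ZNF322 by 0.97 ± 0.48, FAM200C by 0.75 ± 0.50, TUBD1 by 0.72 ± 0.42 and ZNF557 by 0.70 ± 0.44. ATF3 (-1.19 ± 0.95), KLF11 (-0.99 ± 0.55), MAFF (-0.96 ± 0.86) and the matricellular genes CCN2 (-1.14 ± 0.74) and CCN1 (-0.88 ± 0.89) fell. By 24 h CDKN1A fell by 0.49 ± 0.82 in 45 of 59 lines, and MDM2 stood at -0.22 ± 0.57 with probes from -0.22 to 0.07. TOP1 was at -0.16 ± 0.16 at 6 h and 0.07 ± 0.17 at 24 h, and TOP2A at 0.12 ± 0.23 and 0.24 ± 0.54. Limma called 9 genes at 6 h (6 up, 3 down) and 39 at 24 h (18 up, 21 down). With quantile normalization the first split was 5 and 5 of 10, and with centred arrays the second was 12 and 25 of 37. Without the replicate block the count at 24 h was 21, with 14 up and 7 down, so the majority turned. Without HL-60 and MOLT-4 the counts were 11 and 42.

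Whether the response depended on the tissue of origin was tested with a moderated F test over the 9 tissues. At 6 h RNF43, a ubiquitin ligase of Wnt signalling, was at -1.70 ± 0.35 in colon lines (n = 6) and between -0.40 and 0.15 elsewhere. The transcription factor gene SOX5 was at -1.64 ± 0.79 in melanoma lines (n = 8), and PDZRN3 at -2.19 ± 1.07 in melanoma and -1.75 ± 0.83 in CNS lines. NLGN1, a synaptic adhesion protein gene, was at -1.58 ± 0.52 in melanoma lines. SH3BP4 (0.03 ± 0.20), LHFPL2 (0.12 ± 0.36), SASH1 (0.13 ± 0.22) and PPP2R3A (0.21 ± 0.49) were near or above 0 in the 6 leukemia lines and below 0 in each other tissue. At 24 h the cell adhesion gene CHL1 was at -2.43 ± 1.07, the ganglioside synthase gene ST8SIA1 at -2.08 ± 0.96 and NLGN1 at -3.86 ± 0.83 in the 9 melanoma lines. ADAM12, a metalloprotease gene, was at -2.57 ± 0.26 and ZNF282 at 1.47 ± 0.30 in the 5 CNS lines, IKZF1, a lymphoid transcription factor gene, at -1.26 ± 0.41 in the 5 leukemia lines, and the potassium channel gene KCNMA1 at -2.99 ± 0.78 and DOCK2 at -2.23 ± 1.07 in the 8 renal lines. Limma's adjusted p was at most 1.23e-05 at 6 h and 1.89e-06 at 24 h for these genes. At 24 h each of these genes except ZNF282 had a higher untreated level in the tissue of its largest fall than in the other lines. At 6 h the same held for each named gene. For SH3BP4 (9.13 against 8.93), SASH1 (6.76 against 6.36) and PPP2R3A (7.74 against 7.30) the difference was small. The SD over the other lines was 1.90, 1.22 and 1.35. The untreated levels of SH3BP4, LHFPL2, SASH1 and PPP2R3A in leukemia lines were not compared. CHL1 stood at 6.73 ± 1.67 in untreated melanoma lines and 3.44 ± 0.44 in the others, IKZF1 at 8.57 ± 0.90 in leukemia lines and 4.45 ± 0.17 in the others, and RNF43 at 8.0 ± 0.93 in colon lines and 4.45 ± 0.75 in the others. ZNF282 stood at 6.48 ± 0.17 in CNS lines and 6.55 ± 0.44 in the others. A gene with a low untreated level can fall little. The tests over tissues, and the counts below, do not separate this from a different response.

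In all, 417 genes differed between tissues at 6 h and 2731 at 24 h. Without the leukemia lines 127 differed at 6 h, without RPMI-8226 434, and without the CNS lines 1404 differed at 24 h, settings chosen after seeing the data. In tests of each tissue against all other lines, counted with a difference of at least 1.5-fold, the CNS lines had the highest count at 24 h, with 1076 genes (611 higher, 465 lower), followed by leukemia (415), melanoma (258), colon (165), renal (64), breast (5), prostate (4), ovarian (3) and lung (0). At 6 h leukemia lines had 196, melanoma 64, colon 19, CNS 9 and renal 2. At any fold, as in the F test, the counts were 1599 for CNS, 737 for leukemia, 451 for melanoma, 239 for colon and 91 for renal lines at 24 h, and 576 for leukemia, 115 for melanoma and 36 for colon lines at 6 h. No gene passed limma in lung lines at either time. The response size, the root mean square log2 change over all genes, was 0.692 ± 0.081 in the 5 CNS lines and 0.549 ± 0.080 in the other 53 at 24 h (2-sided permutation p = 0.00067). This test was chosen after the result was seen. The corresponding permutation p was 0.857 at 6 h and 0.955 at 2 h. The test at 2 h included the mixed arrays of HL-60 and MOLT-4, and the leukemia lines averaged 0.439 ± 0.184 at that time.

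**Figure D4:**
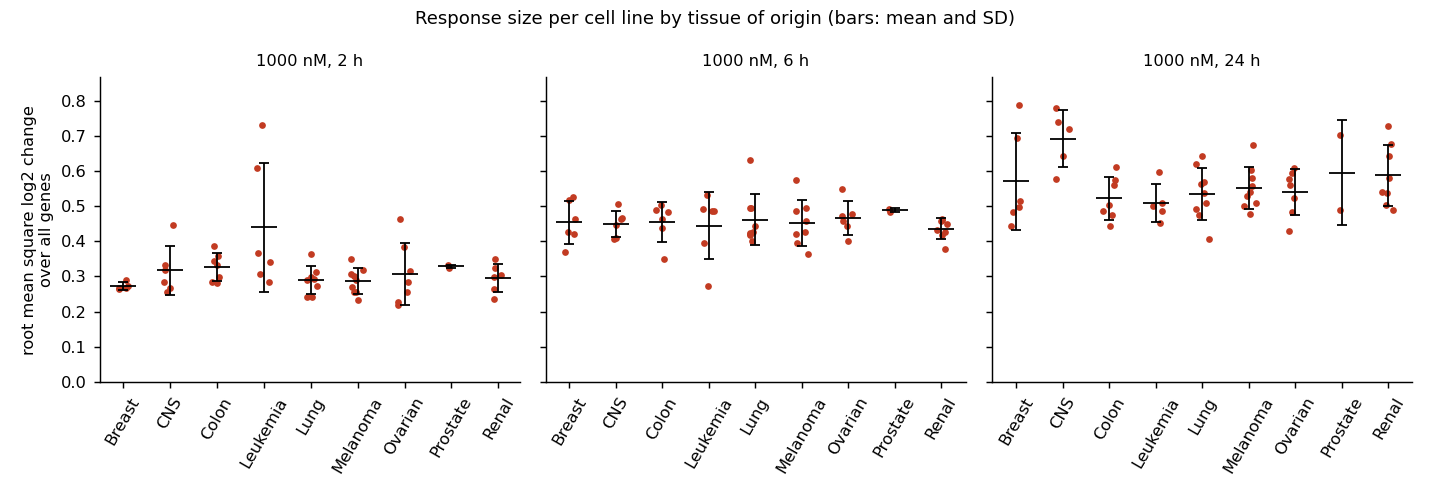
Root mean square log2 change over all genes at 1000 nM (vertical axis) by tissue of origin (horizontal axes) at 2, 6 and 24 h, 1 point per cell line, with bars for the mean and SD. At 24 h the 5 CNS lines averaged 0.692 against 0.549 in the other lines. The leukemia points at 2 h include HL-60 and MOLT-4 with their mixed arrays.

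The relation between gene length and response was examined within each line, as Spearman's rho across 11954 genes between the log2 change and the genomic length in GRCh38.p14. At 1000 nM the mean rho was -0.151 at 2 h (below 0 in 55 of 56 lines), -0.329 at 6 h (57 of 57) and -0.227 at 24 h (58 of 58). The permutation p was 1e-05 in each case, the smallest the permutations can give (adjusted p = 1.5e-05 over 6 comparisons). At 10 nM it was -0.0200 at 2 h (adjusted p = 0.0018), -0.0289 at 6 h (adjusted p = 1.5e-05) and -0.00222 at 24 h (adjusted p = 0.757) by the same permutation test. Among the brightest genes, the median change at 1000 nM and 24 h was 0.12 ± 0.07 for genes under 10 kb, 0.06 ± 0.07 for 20 to 50 kb, -0.35 ± 0.11 for 100 to 200 kb and -0.88 ± 0.22 for 200 to 500 kb. The class over 500 kb held only 12 bright genes (-1.91 ± 0.55). Over all genes, dim ones included, the 200 to 500 kb class was at -0.27 ± 0.07 and the class over 500 kb at -0.16 ± 0.07. Genes are not independent replicates, so the line was the unit of the test.

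**Figure D5:**
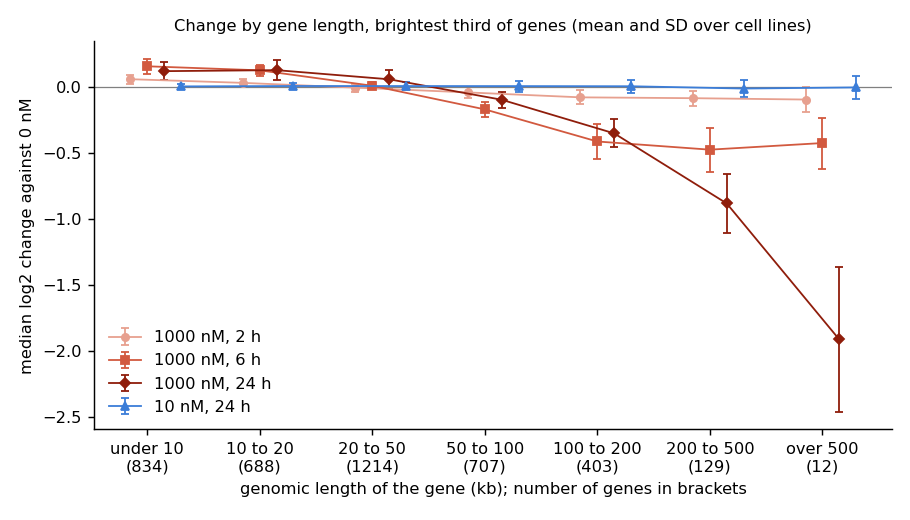
Median log2 change against 0 nM (vertical axis) by genomic length class in kb (horizontal axis, number of genes in brackets) among the brightest genes, as the mean and SD over 56 to 59 lines. At 1000 nM and 24 h the value went from 0.12 under 10 kb to -0.88 at 200 to 500 kb, while at 10 nM and 24 h it stayed between -0.01 and 0.01.

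Baseline expression was set against the 24 h response to 1000 nM over 55 lines, with the baseline from untreated arrays at 2 and 6 h, the mixed HL-60 array at 2 h included. TP53 and SLFN11 were not measured here by a probe with 1 gene, which left 6 genes and 12 relations. In the main setting no Pearson correlation passed Benjamini-Hochberg adjustment in permutation tests. With the p53 target change, MDM2 passed with the mean of all probes (r = 0.470), ABCG2 (0.452), MDM2 (0.384) and CDKN1A (0.438) without leukemia lines, and MDM2 (0.360) and CDKN1A (0.413) with the baseline from 24 h. That 24 h baseline is the untreated array also subtracted in the response, so the 2 are not independent. In every setting MDM2 and CDKN1A are also members of the p53 target list. The highest in the main setting were those with the mean change of the p53 targets for ABCG2, an efflux transporter of camptothecins (r = 0.354, p = 0.00863, adjusted p = 0.0686), MDM2 (r = 0.334, p = 0.0123, adjusted p = 0.0686) and CDKN1A (r = 0.320, p = 0.0171, adjusted p = 0.0686). By rank, MDM2 (rho = 0.439, adjusted p = 0.0113) and CDKN1A (rho = 0.392, adjusted p = 0.0213) passed and ABCG2 did not (rho = 0.326, adjusted p = 0.0604). In the main setting without the 2 lines farthest from the median baseline, r was 0.511 for MDM2, 0.407 for CDKN1A and 0.357 for ABCG2. With the leukemia lines left out as well, r without the 2 farthest lines was 0.418 for MDM2 and 0.427 for CDKN1A. For ABCG2 it was only 0.174, so the pass of ABCG2 without leukemia lines rested on 2 lines. TOP1 had r = 0.106 with the response size (p = 0.442, rho = 0.0162) and 0.241 with the p53 target change (p = 0.0764, rho = 0.219).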

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

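The tests on the mixed arrays of HL-60 and MOLT-4 were chosen only after the result was seen, and the other tests in this part were set down before their results. A sample far from its group was looked for in 40 groups of lines, and 3 were found. Chance flags about 1 in 20 groups, or about 2 of 40, so the number found is near that of chance. The lung line NCI-H522 had a response size of 0.630 at 1000 nM and 6 h, against 0.402 to 0.496 in the other lung lines (9 lines). The colon line HCT-116 had a mean change of p53 targets of 1.64 at 1000 nM and 24 h, against 0.20 to 0.52 in the other colon lines (7 lines). The ovarian line IGR-OV1 had a mean change of p53 targets of 0.95 at the same dose and time, against 0.30 to 0.55 in the other ovarian lines (7 lines). Differences between groups were found by tests of the difference itself: the effect of 1000 nM changed in 632 genes between 2 and 6 h and in 726 between 6 and 24 h, and it differed between tissues for 417 genes at 6 h and 2731 at 24 h. A signal was also found in probe sets that the report does not use. Of 3151 probe sets with no or several gene names, 106 were called at 1000 nM and 24 h (46 higher, 60 lower), against 5 between untreated arrays at 24 and 2 h.

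Chance groupings of the arrays were tested with 100 groupings per comparison, the real one among them. The sign of each line's difference was flipped at random, or for the tissue test the tissue labels were permuted. In every comparison the real grouping was the only 1 of 100 to reach its count. For 1000 nM against 0 nM the real and the highest other counts were 145 and 9 at 2 h, 911 and 93 at 6 h, and 959 and 0 at 24 h. For 10 nM against 0 nM at any fold they were 7 and 1, 383 and 3, and 1276 and 1. For 1000 nM against 10 nM they were 117 and 0, 806 and 1, and 826 and 0. The change between times gave 632 and 0 (2 to 6 h) and 726 and 0 (6 to 24 h), the untreated arrays 9 and 0 (6 h) and 39 and 0 (24 h), and the tissue test 417 and 5 (6 h) and 2731 and 69 (24 h). Chance is therefore an unlikely source of each count. It is not excluded, since 100 groupings cannot give less than 1 of 100 and the number of comparisons was not adjusted for.

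The fall of long genes at 1000 nM and 24 h was weighed against technical explanations. Dim probes could weaken or distort a trend with length, but among the 3987 brightest genes the mean rho was -0.335, below the -0.227 of all genes. The choice of 1 probe per gene is excluded by genes with a single probe set, where the mean rho was -0.171 over 7647 genes and below 0 in 58 of 58 lines. The untreated arrays at 24 against 2 h had a mean rho of 0.0152, which decides nothing about time in culture, since the treated and untreated arrays compared had the same time. A biological explanation in the design is the drug itself, since trapped topoisomerase I may block elongating polymerases more often on a longer gene, and a block of this kind was not measured here.

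The arrays of HL-60 at 0 nM and 2 h and of MOLT-4 at 1000 nM and 2 h match each other, and a swap of their labels and a mixture of the 2 lines were weighed. With swapped labels, the array labelled HL-60 would hold nearly no HL-60 signal, but its estimated share was 54.5%, which excludes a plain swap. A mixture of RNA or cells remains possible, with an estimated HL-60 share of 61.3% in the array labelled MOLT-4, against -10.6% to 3.65% in the 8 other MOLT-4 arrays and 97.7% to 123% in the 8 other HL-60 arrays. Where such a mixture arose cannot be told from these data, and no biological explanation was tested.

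Lines with a larger rise of p53 targets had a lower mean change of G1/S genes at 1000 nM and 24 h (r = -0.603 over 58 lines, rho = -0.465, permutation p = 1e-05 and 0.00027, adjusted p = 4e-05 over 6 relations). That mean was above 0 in some lines, so a lower change was not always a fall. The r without the 2 farthest lines was -0.652. G2/M genes gave a similar relation (r = -0.541, rho = -0.519, permutation adjusted p = 7e-05), so it was not particular to G1/S genes. Arrays shared by both readouts could create such a relation. With p53 targets taken at 6 h, r was -0.621 for G1/S and -0.553 for G2/M genes over 55 lines, which excludes shared arrays as the only source. Differences between tissues are excluded as the only source by r = -0.611 for G1/S and -0.535 for G2/M genes after the tissue means were subtracted. A biological explanation is that lines with a working p53 pathway may leave the cell cycle more completely, but the p53 status of the lines is not in these records and was not tested.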

How the results depend on the processing

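The settings without HL-60 and MOLT-4, RPMI-8226, the CNS lines, and leukemia lines in the tissue test were chosen only after the results were seen. Of 286 alternative values for comparisons, 261 stayed on their side, 19 moved and 6 became stronger. For lists 408 of 456 stayed, 44 became weaker (28 with an estimated correlation) and 4 stronger. The 456 include list tests that were not calls in the main setting and could not become weaker. For named genes 6583 of 7004 stayed, 379 became weaker, 36 stronger and 6 reversed. Called counts at 1000 nM ranged over 110 to 146 (2 h), 754 to 952 (6 h) and 812 to 1047 (24 h). The strength of signal over background limits dim genes, and changes there are compressed by an unknown amount. Except where another reason is given, the cause was not tested.

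Without the pairing by line (no replicate block), the genes that passed at 10 nM at any fold went from 7 to 0 at 2 h, from 383 to 0 at 6 h and from 1276 to 0 at 24 h, the 1 called gene at 6 h to 0, and the 39 of untreated 24 h to 21. With all arrays in 1 fit with the replicate block, the 10 nM counts were 0, 37 and 134. The block moved no other count of called genes by over 1.5 times. For 10 nM at 2 h, 4 genes passed with the mean of all probes, 4 with centred arrays, 3 with only the lines that have all 9 arrays, 4 without the lines of shared origin and 4 without leukemia lines. The tissue counts were 127 without leukemia lines (6 h) and 1404 without CNS lines (24 h), with fewer lines and tissues tested. Correlations of the doses were 0.151, 0.302 and 0.266 with lines split into 2 sets that share no control, and 0.435 at 6 h without dim genes.

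For baseline and the change of p53 targets, settings that passed were MDM2 with the mean of all probes (r = 0.470), ABCG2 (0.452), MDM2 (0.384) and CDKN1A (0.438) without leukemia lines, and MDM2 (0.360) and CDKN1A (0.413) with the baseline from 24 h. The setting with the 24 h baseline shares its untreated array with the response. The value of ABCG2 without leukemia lines went to 0.174 when the 2 lines farthest from the median baseline were also left out. MDM2 reversed at 1000 nM and 2 h with the mean of all probes (-0.079). With _x_at probes left out, which selects another probe, MDM2 reversed at 1000 nM and 6 h (-0.28), in 1000 against 10 nM at 6 h (-0.34), between 2 and 6 h (-0.20) and in untreated cells at 24 h (0.068), as did GDF15 at 10 nM and 24 h (-0.013).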

Other observations

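The gene families in this part and their 66 tests were chosen only after the results were seen. Zinc finger genes of the ZNF family changed direction with time at 1000 nM. Their 235 members averaged -0.16 ± 0.07 at 2 h (below 0 in 55 of 56 lines, 13 rose and 110 fell), 0.12 ± 0.10 at 6 h (above 0 in 53 of 57 lines, 123 rose and 44 fell) and 0.25 ± 0.19 at 24 h (above 0 in 55 of 58 lines, 163 rose and 15 fell). The 34 ubiquitin-specific protease genes (USP) averaged -0.09 ± 0.05 at 2 h and -0.26 ± 0.08 at 6 h, where 57 of 57 lines were below 0, 9 rose and 17 fell. The 8 metallothionein genes, which encode metal-binding proteins, averaged 0.15 ± 0.19 at 2 h (7 rose) and 0.18 ± 0.25 at 6 h (8 rose), and -0.34 ± 0.42 at 24 h (7 fell). HLA genes, which present antigens, averaged 0.17 ± 0.09 at 6 h and 0.30 ± 0.19 at 24 h, above 0 in every line, and 14 of 21 rose at 24 h. The dual-specificity phosphatase genes (DUSP) averaged 0.41 ± 0.23 at 24 h, where 12 of 17 rose and 1 fell, and genes of mitochondrial complex I (NDUF) averaged 0.07 ± 0.04 at 2 h, where 26 of 34 rose. The adjusted permutation p was 2.4e-05 for each of these values. That test set each family mean against 0 and not against other genes. Of all 11963 genes, 1924 rose and 2025 fell at 2 h, 4498 and 2977 at 6 h, and 3676 and 2644 at 24 h. The brightest genes under 10 kb had a median change of 0.06 ± 0.03 at 2 h and 0.16 ± 0.06 at 6 h. The NDUF value at 2 h and the HLA value at 6 h were near these. At 2 h the median over all genes was 0.01, or 0.07 with centred arrays. The DUSP genes at 2 h changed sign between settings and did not pass (adjusted p = 0.861). Median gene lengths were 23.8 kb for ZNF, 63.4 kb for USP and 1.33 kb for metallothionein genes.

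Lines differed widely at 1000 nM and 24 h. CDKN1A rose by 0.65 in HOP-92 and by 6.31 in MOLT-4. The mean change of p53 targets ran from 0.14 in NCI-H522 to 2.31 in NCI-H460, that of interferon genes from -0.29 in SK-OV-3 to 2.97 in HT29, that of NF-kB targets from -0.02 in UACC-62 to 3.40 in NCI-H226, and that of G2/M genes from -3.23 in MCF7 to 0.34 in SK-MEL-28. The number of genes changed at least 2-fold ran from 370 in NCI-ADR-RES to 1848 in SF-539. At 1000 nM and 2 h MOLT-4, whose array at that time held signal of both leukemia lines, had 1175 such genes, against a mean of 149.

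The RPMI-8226 array at 1000 nM and 6 h was closer in size to the 10 nM array of the same line than to other lines at 1000 nM. Its response size was 0.272 at both doses, its G2/M list changed by -0.26 at 1000 nM and -0.25 at 10 nM, CDKN1A by 0.32 and 0.19, and the p53 target list by 0.07 and 0.14. Across genes, however, its change at 1000 nM and 6 h correlated with the mean 10 nM change of the other lines at only r = 0.0645. That was the lowest of all lines at 1000 nM and 6 h, with OVCAR-4 next at 0.185. At 24 h of 1000 nM RPMI-8226 had a response size of 0.50 and a long gene list at -1.07. No explanation of this array was tested.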
